A study of Mus musculus with 3 samples.

How the data were processed

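The data were 10x Visium spatial libraries of fresh frozen, 10 µm sections of mouse brain (strain C57BL/6J), 3 sections in 3 groups of 1. Visium captures polyadenylated RNA of a tissue section on an array of barcoded spots and counts molecules by unique molecular identifiers (UMIs). The labels name the molecule as nuclear RNA, although the protocol describes whole sections placed on the array, and the values were read as RNA of the tissue under each spot. Groups followed the titles and the treatment label: Y-Ctrl and O-Ctrl are controls and O-Ex is exercise. Ages, the length and kind of exercise and the number of animals are not given in the sources used here.

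The deposited matrices held raw whole-number UMI counts of 31053 genes for 4992 barcodes per section, without normalization. They were made with Space Ranger 2.0.0, per the file headers, and aligned to mm10, per the submitters' processing notes. Spot positions and images were not used here, so regions were defined from expression alone. Gene symbols and IDs were those of the deposited files, where 71 symbols are held by more than 1 ID. Coordinates and transcript lengths were taken from the GENCODE mouse annotation given for mm10, counting from 1.

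The matrices hold every barcode, tissue or not. Spots over tissue were those above the minimum of the density of log10(UMI + 1) between 2 and 3.7 on that scale (Gaussian kernel, bandwidth 0.1), with 1000 UMIs as the fallback. The minimum fell at 1364 UMIs in Y-Ctrl, 2984 in O-Ctrl and 210 in O-Ex. The value for O-Ex is low and keeps many shallow spots, so minimums of 1000 and of 3000 UMIs were run as alternatives. Tissue spots held 99.2%, 97.9% and 99.9% of all UMIs. No doublet caller was run, since a spot is a piece of tissue.

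Tissue spots of the 3 sections were clustered together with scanpy 1.11.5. Counts were scaled to 10000 per spot and log-transformed, genes in at least 10 spots were kept, and the 2000 most variable genes were scaled within each section (clipped at 10). Then 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.8 (igraph 0.11.9) were used. Genes of 22 of the 34 fixed lists, those without a region of their own, took no part in choosing clusters. A cluster was named for a region when at least 4 of that region's fixed markers were among its 30 leading genes by CPM ratio (pseudocount 20 CPM). Clusters whose median UMI count was under 1/3 of the section's stayed unnamed. The markers were fixed in advance, but this naming rule was chosen after the clusters were seen. Clusters with at least 50 spots in every section were called shared regions. A cluster found mostly in 1 section may be that section and not a region, so shares were described and not compared by a test.

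Counts were summed over the spots of a section, or of a region in a section, and expressed as CPM, scaled to the same total of all UMIs. The log2 ratio of 2 sections was taken on CPM plus a pseudocount of 5, which understates differences of genes with few counts. A region-matched ratio is the equal-weight mean of this log2 ratio over the shared regions. Genes with a mean of at least 10 CPM entered the counts, and a size of 1.5-fold was used to describe them. The comparisons were O-Ctrl over Y-Ctrl, O-Ex over O-Ctrl, and the relation between these ratios across genes. Because each group has 1 section, no test was run and spots were not treated as replicates. CPM have exact 95% Poisson intervals and shares exact 95% binomial (Clopper-Pearson) intervals. A count of 0 was given the limit of 3 counts.

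Genes were named by a rule: for each comparison the 8 highest and the 8 lowest region-matched log2 ratios among genes with the same direction over the whole section and in every shared region with at least 20 counts, leaving out region markers and sex-linked genes. In addition, the 2 most abundant members and the 2 with the largest ratios of each list could be named. So could the highest and the lowest gene with at least 100 counts in each shared region, again leaving out region markers and sex-linked genes. The 34 lists covered microglia, complement, interferon, MHC, astrocytes, oligodendrocytes, vessels, meninges, choroid plexus, ependyma, blood, immune cells, pituitary, neurons, activity, neurotrophic factors, respiration, ribosomes, chaperones, the clock, glucocorticoids, senescence, cholesterol, lysosomes and sex. Of their symbols 3 were not matched. A list with at least 3 measured members was described by its median ratio and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins (2000 random lists in the alternatives). Members of lists with fewer were named after their values were seen. The percentile describes these libraries and is no test across animals. Some genes belong to more than 1 list, and a few single genes are not reported here. These groups, lists, markers, thresholds and rules were fixed before the data were examined, except where stated.

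The steps were tested on simulated data: counts drawn for 9014 genes per comparison from the real means, with 200 genes altered. All altered genes had the right direction in both comparisons. The share past 1.5-fold was 17.65% of 68 genes altered 1.5-fold in each comparison, 95.5% and 98.5% of 66 genes altered 2-fold in the age and the exercise comparison, and 100% of 66 genes altered 4-fold in each. Among unaltered genes 0 passed that size after region matching in either comparison, and 2 and 25 did over the whole section. Of 200 random lists, 4.0% and 2.5% stood apart. The relation between the comparisons was set against 100 simulated sets of sections without differences, since both share O-Ctrl, and against 20 random splits of the O-Ctrl spots into a pair of sets. Genes picked on the age ratio were also counted in 100 simulated sets in which O-Ctrl and O-Ex were drawn from their pooled counts, a step chosen after the results were seen.

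The alternatives were TMM-scaled library sizes (edgeR 4.0.16 in R 4.3.3), CPM without mitochondrially encoded genes, mean CPM minimums of 2 and 50, a pseudocount of 1, a size of 2-fold, spots with at least 1000 or 3000 UMIs, spots thinned to 3133 UMIs, Leiden resolutions of 0.4 and 1.5, no scaling within sections, spots given to the region of highest marker score, regions weighted by their spots, each shared region left out, and whole sections. Chosen after seeing the data were the ratios without the shared cluster of low depth, clustering without the named genes, the split of O-Ctrl, list medians without mitochondrially encoded genes, and ratios less the median of genes of like transcript length in 20 bins. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.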

Results

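Gene expression was mapped across 3 mouse brain sections, 1 in each group, with a capture array that records RNA from small spots of tissue. A spot can hold parts of several cells, so every value below belongs to spots or regions and not to single cells. The groups were a control section with the prefix Y (Y-Ctrl), a control section with the prefix O (O-Ctrl) and a section from an exercised mouse with the prefix O (O-Ex). The series concerns exercise and the aging brain, so O and Y were read here as old and young, although the labels give no ages. Total counts of unique molecular identifiers (UMIs) were 62348064 in Y-Ctrl, 58234443 in O-Ctrl and 53196124 in O-Ex. Spots over tissue numbered 3722, 3498 and 4391, with a median of 14971, 14900 and 9750 UMIs and of 4108.5, 4149.5 and 3206 detected genes. The lower median of O-Ex came with a tissue minimum of 210 UMIs, against 1364 in Y-Ctrl and 2984 in O-Ctrl. With every spot thinned to 3133 UMIs, which left out 331, 11 and 1098 spots, the median number of genes was 1521, 1512 and 1568. Mitochondrially encoded transcripts took 19.7%, 19.7% and 17.8% of tissue UMIs. With 1 section per group no difference below has a replicate check, no test was possible, and section, animal and condition could not be separated. Intervals in brackets are exact 95% Poisson intervals for UMI counts scaled to a common total (CPM) and exact 95% binomial intervals for shares, and cover counting error only.

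Joint clustering of the spots gave 23 clusters, of which 15 held at least 50 spots in every section and served as shared regions. The shared regions held 75.3% of the spots of Y-Ctrl, 89.5% of O-Ctrl and 82.3% of O-Ex. White matter held 9.94% [8.998 to 10.9] of spots in Y-Ctrl, 11.2% [10.2 to 12.3] in O-Ctrl and 7.65% [6.88 to 8.48] in O-Ex. A thalamic region led by Prkcd, a protein kinase C gene, held 10.0%, 7.06% and 5.26% of spots, and a hypothalamic region led by Pmch, the gene of melanin-concentrating hormone, held 4.30%, 9.21% and 6.70%. Upper cortical layers held 10.1%, 8.29% and 7.52%, layer 6 cortex 5.83%, 5.83% and 4.03%, the ependyma and ventricle wall 2.26%, 1.97% and 1.87%, and the meninges 1.42%, 2.20% and 1.57%. Other clusters had uneven numbers of spots, and whether the sections were cut differently was not tested. A second thalamic region held 253 spots in Y-Ctrl and 5 in each of the other sections, and striatum held 169, 175 and 28 spots. Choroid plexus, the epithelium that makes cerebrospinal fluid, held 53, 35 and 98 spots, hippocampal CA1 36, 29 and 35, and the dentate gyrus 26, 23 and 29. An unnamed cluster of low depth was shared but weighted towards O-Ex, with 53, 60 and 605 spots at a median of 1808, 4746 and 655 UMIs. Another cluster of low depth, not shared, held 321, 45 and 547 spots at a median of 2553, 3825 and 1965 UMIs. Such spots count in the total of each section and lower the shares of all other regions, most in O-Ex with its low tissue minimum. A lower share in O-Ex therefore need not mean less of a region. Differences between sections were therefore taken within shared regions and averaged over them with equal weight, and are called region-matched. CPM are those of whole sections unless a region is named, and carry no pseudocount. The log2 ratios and folds of genes, whole-section or region-matched, were taken on CPM plus 5. The quotient of printed CPM can therefore exceed the ratio beside it, most for genes with few counts.

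The first comparison, O-Ctrl over Y-Ctrl, asked how the control brain differed with age. Transcripts of interferon-responsive genes, complement, reactive astrocytes and microglia were higher in the O-Ctrl section, while activity-dependent and excitatory neuronal transcripts were lower. Gbp2, an interferon-induced guanylate-binding protein, stood highest: 3.48 CPM [3.03 to 3.97] in Y-Ctrl and 32.1 CPM [30.7 to 33.6] in O-Ctrl, a region-matched log2 ratio of 2.15, or 4.43-fold. C4b, a complement component, was at 15.2 CPM [14.3 to 16.2] and 90.8 CPM [88.4 to 93.3], 2.97-fold higher in the O-Ctrl section after region matching and 4.74-fold over the whole sections. Nptx2, a pentraxin that gathers glutamate receptors at synapses, was at 33.5 CPM [32.1 to 35.0] and 19.8 CPM [18.6 to 21.0], 1.84-fold lower in the O-Ctrl section.

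Most genes lay close together in these 2 control sections. Of 9014 genes with a mean of at least 10 CPM, 99.6% were within 1.5-fold after region matching, 23 were at least 1.5-fold higher and 11 at least 1.5-fold lower in O-Ctrl, and the median log2 ratio of all genes was 0.01. The higher genes made up 67.6% of these, against 84.6% (22 to 4) without scaling within sections before clustering and 82.8% (24 to 5) without the shared cluster of low depth. Over the whole sections, where unequal shares of regions enter, 33 were higher and 22 lower. The 11 region-matched lower genes include region markers, which the naming rule left out: Pmch (log2 ratio -1.56), Hcrt (-1.12), Ramp3 (-0.63), Prkcd (-0.60) and Tac2 (-0.59). Pmch and Hcrt had the lowest ratios of the 11. Whether the matched clusters held the same tissue in both sections was not tested. The 8 genes named as highest were higher in all 15 shared regions, which the naming rule required wherever a region held at least 20 counts. After Gbp2 and C4b these were Igtp, an interferon-induced GTPase (log2 ratio 1.505, 5.4 to 25.1 CPM), Serpina3n, a protease inhibitor of reactive astrocytes (1.31, 10.3 to 34.9 CPM), Ly6a, a surface antigen of endothelial and other cells (1.27, 53.3 to 131 CPM), and AW112010, an interferon-responsive RNA (1.26, 6.00 to 20.3 CPM). Gfap, the intermediate filament of astrocytes, followed with 0.98 and 50.5 to 128 CPM. AC149090.1 (1.23, 61.9 to 147 CPM) is annotated on the unplaced scaffold JH584304.1, so reads of similar sequence placed elsewhere leave its value uncertain.

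In mm10 coordinates, Gbp2 (ENSMUSG00000028270) lies on chromosome 3 at 142620602 to 142638008, C4b (ENSMUSG00000073418) on chromosome 17 at 34728380 to 34743882, and Igtp (ENSMUSG00000078853) on chromosome 11 at 58199556 to 58207591. Serpina3n (ENSMUSG00000021091) lies on chromosome 12 at 104406729 to 104414329, and Nptx2 (ENSMUSG00000059991) on chromosome 5 at 144545902 to 144557478. All are annotated as protein coding.

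The 8 genes named as lowest in O-Ctrl were lower in all 15 shared regions, as the same rule required in regions with at least 20 counts. Bc1, a short noncoding RNA that represses translation in dendrites, was the most abundant, at 10830 CPM in Y-Ctrl and 7526 CPM in O-Ctrl (log2 ratio -0.64). Cck, the gene of the neuropeptide cholecystokinin, was at 1274 and 1076 CPM (-0.53), and its whole-section ratio was -0.24. Rgs4, which shortens G protein signals, was at 239 and 165 CPM (-0.48), Gabra4, a GABA-A receptor subunit, at 108 and 73.2 CPM (-0.49), and Lzts3, a protein of dendritic spines, at 35.0 and 22.2 CPM (-0.54). Tmem267 (-0.68, 14.8 and 7.56 CPM) and Lrrc17 (-0.45, 38.8 and 29.8 CPM) completed the group with Nptx2 (-0.88). Some of these means leaned on few regions. In the shared cluster of low depth Cck was at -2.19, Gabra4 at -2.04 and Rgs4 at -1.77. In upper cortical layers these genes were at -0.02, -0.16 and -0.33.

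**Figure D1:**
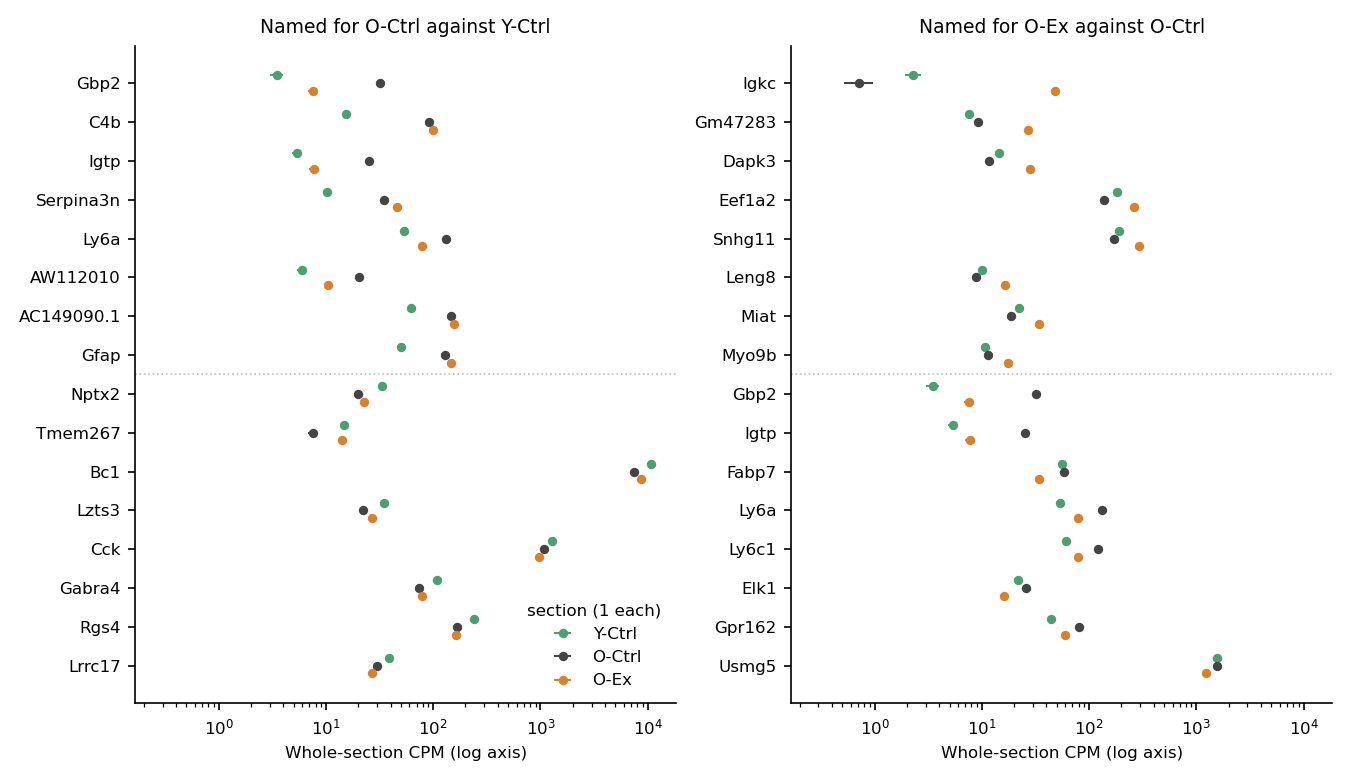
Whole-section CPM (log axis) of the genes named for each comparison, with the higher genes above and the lower genes below the dotted line; points are the 3 sections, 1 per group, and bars are exact 95% Poisson intervals. Gbp2 was at 3.48 CPM in Y-Ctrl, 32.1 CPM in O-Ctrl and 7.56 CPM in O-Ex, whereas C4b was at 15.2, 90.8 and 100.5 CPM.

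Gene lists fixed in advance were read by the median region-matched log2 ratio of their members and its percentile among 10000 random lists matched on expression, with lists among the lowest or highest 2.5% of these said to stand apart. Of 30 lists with enough measured members, 9 stood apart as higher in O-Ctrl, 3 as lower, and 18 did not stand apart. Reactive astrocyte genes had the highest median, 0.98 with 5 of 5 members higher (percentile 100), and Vim, another intermediate filament, was at 41.5 and 60.3 CPM. Gbp2 and Serpina3n belong to this list, so it is not separate from the genes named above. MHC class I genes, which present peptides to T cells, were higher for 6 of 6 members (median 0.49, percentile 100), with B2m at 211 and 286 CPM and the immunoproteasome subunit Psmb8 at 6.06 and 17.4 CPM (log2 ratio 0.82). Interferon response genes were higher for 8 of 8 members (0.43, percentile 100), among them the antiviral membrane proteins Bst2 (0.81) and Ifitm3 (0.73). Complement genes were higher for 4 of 5 members (0.43, percentile 99.99), and C1qa, a chain of the initiating complex, was at 68.5 and 119.5 CPM.

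Microglial and lysosomal genes lay higher in the same section. Disease-associated microglia genes were higher for 9 of 10 members (median 0.27, percentile 100), with the lysozyme gene Lyz2 at 12.9 and 36.0 CPM (log2 ratio 0.98), the signalling adaptor Tyrobp at 59.2 and 97.3 CPM and the lipid carrier Apoe at 1456 and 1927 CPM. Homeostatic microglia genes were split, with 8 of 12 higher (0.12, percentile 99.4): Trem2, a lipid-sensing receptor, had a log2 ratio of 0.50 and P2ry12, a purine receptor of resting microglia, one of -0.37. This list no longer stood apart with regions weighted by their spots (0.06, percentile 86.5). All 18 lysosome genes were higher (0.18, percentile 100), including the proteases Ctsd (0.34) and Ctsb (0.29). Myelin genes had a median of 0.07 with 10 of 16 higher (percentile 99.6), with Mobp, a structural protein of the sheath, at 0.32 and Opalin, another myelin protein, at -0.36. They no longer stood apart without scaling within sections before clustering (0.03, percentile 84.1). Ribosomal protein genes stood apart with a median of 0.02 and 57 of 81 higher, but that median was -0.0068 with spots clustered at a resolution of 1.5, -0.0136 without scaling within sections and -0.0029 with regions weighted by their spots.

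Immediate early genes, which neurons transcribe after activity, were lower in O-Ctrl for 13 of 15 members, with a median of -0.24 at percentile 0. Egr1 was at 129 CPM in Y-Ctrl and 85.6 CPM in O-Ctrl, and Arc, whose product reaches active synapses, at 62.0 and 27.8 CPM, with a region-matched log2 ratio of -0.62, lower in 12 of 15 regions. Excitatory projection neuron genes were lower for 9 of 9 members (-0.19, percentile 0), with the transcription factor Mef2c at -0.34. The vesicular glutamate transporter Slc17a7 had a ratio of -0.41 but was higher in 8 of 15 regions and had a whole-section ratio of 0.09. Without scaling within sections before clustering, this list no longer stood apart (-0.04, percentile 7.05). Synaptic genes were lower for 19 of 24 members (-0.12, percentile 0), including the postsynaptic scaffold Shank3 at -0.63, although the median was 0.004 without that scaling.

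Within regions, genes were ranked with region markers and sex-linked genes left out. Gbp2 had the highest ratio of the ranked genes in thalamus (44.2 and 2.47 CPM), upper cortical layers (27.9 and 2.14 CPM) and layer 6 cortex (23.01 and 1.31 CPM). In white matter the highest was Serpina3n, at 162 CPM [150 to 174] in O-Ctrl and 10.5 CPM [7.62 to 14.2] in Y-Ctrl, a log2 ratio of 3.43, whereas in upper cortical layers its ratio was 0.06. In the meninges the iron-binding protein Lcn2 was highest, at 114 and 10.5 CPM. Arc was the lowest gene in layer 6 cortex (-1.41) and in upper cortical layers (-1.18), Bc1 in thalamus (-0.99), the neuropeptide gene Vip in white matter (-1.85), the neuropeptide gene Cartpt in hypothalamus (-2.07) and the endothelial phosphatase Ptprb in the meninges (-1.44). Extreme genes that also lead the cluster they were found in were left out of this ranking. In the ependyma and ventricle wall they differed widely. There Sspo was at 484.5 and 2.245 CPM in O-Ctrl and Y-Ctrl, and Gm5741 had 0 and 1103 counts. The spots of that cluster may therefore not be alike in the 2 sections, and Nptx2 had its lowest ratio (-3.03) there.

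**Figure D2:**
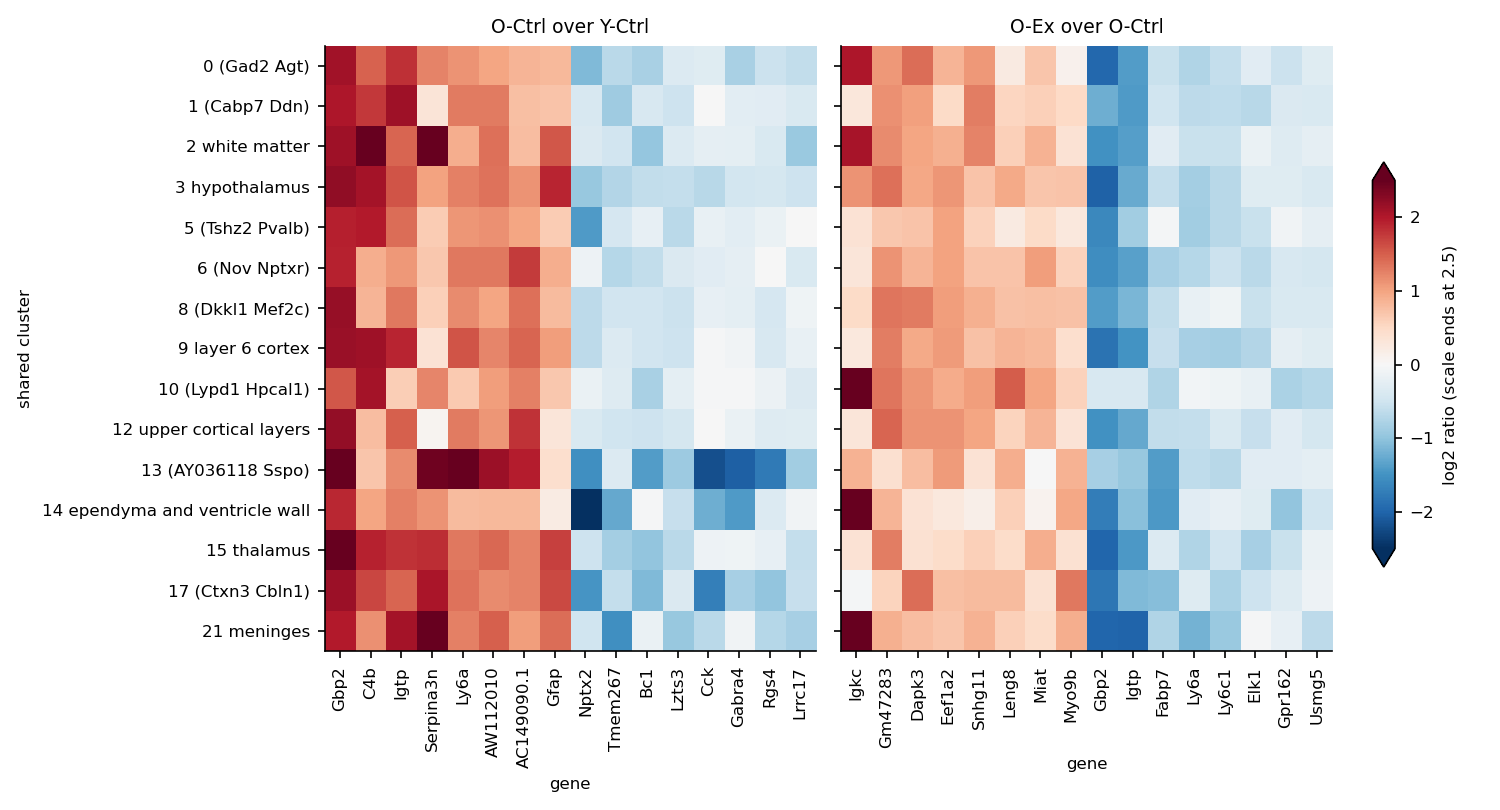
Log2 ratios of the named genes (columns) in each of the 15 shared clusters (rows, numbered, with a region name or 2 leading genes) for O-Ctrl over Y-Ctrl and O-Ex over O-Ctrl; red is higher in the first section of each pair and the scale ends at 2.5. Gbp2 was higher in O-Ctrl in all 15 clusters on the left and lower in O-Ex in all 15 on the right, while Serpina3n ranged from 0.06 to 3.43 on the left.

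The other 18 lists did not stand apart between O-Ctrl and Y-Ctrl. Their medians were 0.04 for astrocyte identity, -0.06 for oligodendrocyte precursors, -0.06 for endothelial, -0.08 for mural and 0.04 for meningeal fibroblast genes. They were -0.01 for choroid plexus, 0.05 for ependymal cilia, 0.04 for erythrocyte, -0.01 for neurotrophic and exercise-linked, 0.04 for GABA interneuron and -0.02 for neurogenesis genes. Mitochondrially encoded respiratory genes had a median of -0.02, nuclear encoded ones 0.00, chaperones 0.05, circadian clock genes 0.00, glucocorticoid response genes 0.03, senescence genes 0.11 and cholesterol synthesis genes 0.06. Some of these lists stood apart under an alternative: erythrocyte genes as higher at a clustering resolution of 1.5 (0.30) and as lower without scaling within sections (-0.24), meningeal fibroblast genes at 0.4 (0.21), GABA interneuron genes as higher over the whole sections (0.18) and as lower at a resolution of 1.5 (-0.08), and endothelial genes without the shared cluster of low depth (-0.10). Over the whole sections meningeal fibroblast (0.14), choroid plexus (0.18), chaperone (0.05), senescence (0.12) and cholesterol synthesis (0.06) genes also stood apart as higher and neurogenesis genes (-0.14) as lower. Ly6a and Ly6c1 (61.0 and 121 CPM) are in the endothelial list, and its other 11 measured members had a median of -0.0977. The mean of the endothelial (0.07), oligodendrocyte precursor (0.01) and choroid plexus (0.04) lists had the opposite sign to the median. MHC class II, peripheral immune, pituitary hormone and sex-linked lists had too few measured members for a median. Cd74, the invariant chain of MHC class II, was at 4.79 CPM [4.26 to 5.36] in Y-Ctrl and 10.1 CPM [9.31 to 10.98] in O-Ctrl, and H2-Aa at 2.49 and 7.21 CPM. Pomc, a hormone precursor gene, was at 7.47 and 8.00 CPM.

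The second comparison, O-Ex over O-Ctrl, asked how the brain of the exercised mouse differed from the control with the same prefix. Gbp2, Igtp, Ly6a and Ly6c1, which were high in O-Ctrl, were lower in the O-Ex section, whereas C4b, Serpina3n, Gfap and the lysosomal genes were not. Choroid plexus, blood and meningeal transcripts were higher in O-Ex, as was the antibody gene Igkc. Gbp2 was at 32.1 CPM [30.7 to 33.6] in O-Ctrl and 7.56 CPM [6.84 to 8.34] in O-Ex, a log2 ratio of -1.56, or 2.94-fold lower. Igtp was at 25.1 CPM [23.8 to 26.5] and 7.71 CPM [6.99 to 8.50], 2.35-fold lower. Igkc, the constant region of antibody light chains made by plasma cells, was at 0.719 CPM [0.516 to 0.976] in O-Ctrl, 2.28 CPM in Y-Ctrl and 47.7 CPM [45.8 to 49.6] in O-Ex. Its log2 ratio was 3.20 over the whole sections and 1.54 after region matching.

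Of the 9014 genes, 99.6% were within 1.5-fold after region matching, 28 were at least 1.5-fold higher in O-Ex and 6 at least 1.5-fold lower, so 82.4% of these lay higher. After each ratio was centred on genes of like transcript length the split was 28 to 2, or 93.3%. It was 21 to 7, or 75.0%, with TMM scaling, 29 to 15, or 65.9%, with genes down to 2 CPM, and 4 to 2, or 66.7%, at 2-fold. Over the whole sections 63 were higher and 12 lower. The median log2 ratio of all genes was 0.07, which TMM scaling moved by -0.06. Across genes the ratio followed transcript length, with a Spearman's rho of 0.35 over 9009 genes, which are not independent replicates. Genes in the shortest of 20 length bins (median 823 nucleotides) had a median ratio of -0.08, and those in the longest (10593 nucleotides) one of 0.13.

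**Figure D3:**
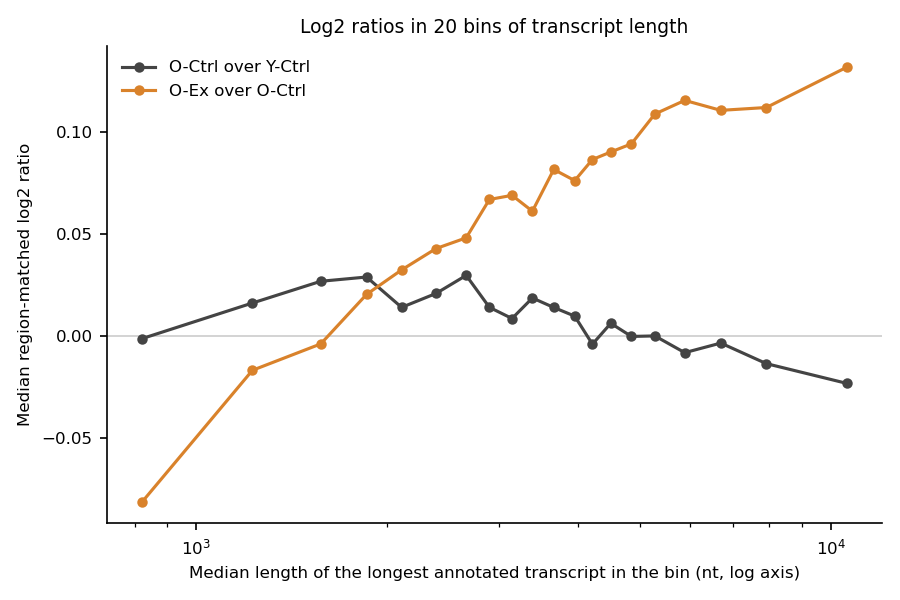
Median region-matched log2 ratio (y axis) in 20 bins of transcript length (x axis, nucleotides, log axis) for both comparisons; each point is a bin of about 450 genes and no error bars are drawn. The O-Ex over O-Ctrl medians ran from -0.08 in the shortest bin to 0.13 in the longest, and the O-Ctrl over Y-Ctrl medians stayed between -0.02 and 0.03.

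The genes named as higher in O-Ex held that direction in all 15 shared regions, apart from Igkc and Miat with 14 of 15. This was set by the naming rule for regions with at least 20 counts. Eef1a2, a translation elongation factor of neurons and muscle, was at 137 CPM in O-Ctrl and 264 CPM in O-Ex (log2 ratio 0.85), and Snhg11, a small nucleolar RNA host gene, at 170 and 295 CPM (0.80). Dapk3, a death-associated protein kinase, was at 11.8 and 28.0 CPM (0.94), Miat, a long noncoding RNA kept in the nucleus, at 18.7 and 33.9 CPM (0.64), Leng8 at 8.79 and 16.4 CPM (0.68), and Myo9b, an unconventional myosin, at 11.3 and 17.4 CPM (0.60). Gm47283 was at 9.28 and 26.7 CPM (1.06), but is annotated on chromosome Y at 90784738 to 90816464, while the Y genes Ddx3y, Uty and Eif2s3y had 0 counts in each section, which allows up to 0.0564 CPM in O-Ex, and Kdm5d had 2, 1 and 1. Reads shared with a copy elsewhere in the genome leave its value uncertain. Xist, the RNA of the inactive X chromosome, was at 18.7 CPM in Y-Ctrl, 24.1 CPM in O-Ctrl and 40.5 CPM in O-Ex.

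Genes named as lower in O-Ex were lower in all 15 shared regions, again by the naming rule where a region held at least 20 counts. Besides Gbp2 and Igtp these were Ly6a (131 and 78.8 CPM, log2 ratio -0.61), Ly6c1 (121 and 79.2 CPM, -0.55) and Fabp7, a fatty acid binding protein of astrocytes (57.9 and 34.1 CPM, -0.69). Elk1, a transcription factor of the MAP kinase pathway, was at 25.98 and 15.98 CPM (-0.44), Gpr162, an orphan receptor, at 81.0 and 60.1 CPM (-0.40), and Usmg5, a small subunit of ATP synthase, at 1548 and 1222 CPM (-0.36). AW112010 had a ratio of -0.66 but was lower in 14 of 15 regions.

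Of the 30 lists, 14 stood apart as higher in O-Ex, 3 as lower, and 13 did not stand apart. Erythrocyte genes had the highest median, 0.87 with 4 of 4 higher (percentile 100), and the haemoglobin gene Hbb-bs was at 550 and 1013 CPM. Choroid plexus genes were higher for 8 of 8 members (0.63, percentile 100), with Ttr, the thyroid hormone carrier, at 4864 and 12420 CPM and Enpp2, a lipid-making phosphodiesterase, at 597 and 1302 CPM. Outside the choroid plexus cluster Ttr was at 992 CPM in O-Ctrl and 2058 CPM in O-Ex, and it was higher in O-Ex in each shared region apart from white matter (5543 and 1605 CPM). The difference was uneven, from 462 and 18730 CPM in a cluster led by Lypd1 to 297 and 335 CPM in a cluster led by Tshz2. Meningeal fibroblast genes were higher for 4 of 4 members (0.38, percentile 100), with the matrix protein Mgp at 52.4 and 84.8 CPM, but did not stand apart once genes down to 2 CPM were counted (0.15, percentile 96.5). Ependymal cilia genes were higher for 10 of 10 members (0.30, percentile 100), with Calml4 at 15.2 and 42.9 CPM, a log2 ratio of 1.25 over the whole sections but of 0.44 after region matching, higher in 10 of 15 regions. Endothelial genes were higher for 10 of 13 members (0.25, percentile 100), including Bsg at 0.25, while Ly6a and Ly6c1 of that list were lower.

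Glial and immune lists took separate courses. Interferon response genes had a median of -0.07 with 4 of 8 lower (percentile 0.12), among them Bst2 at -0.22 and Ifitm3 at -0.18, but their whole-section median was 0.001. MHC class I genes did not stand apart (0.02): Psmb8 had a ratio of -0.20 and H2-K1 one of 0.29. Complement genes were higher for 5 of 5 members (0.27, percentile 99.95), with C4b at 0.35, though their whole-section median of 0.12 did not stand apart. Reactive astrocyte genes had a median of 0.20 (percentile 97.7) but a mean of -0.17, since Gfap (0.23) and Vim (0.43) were higher and Gbp2 lower. They did not stand apart with genes down to 2 CPM (0.05, percentile 38.6), without the meninges (0.13, percentile 84.4), at a clustering resolution of 0.4 (0.16, percentile 90.1), with clustering without the named genes or over the whole sections. Lysosome genes were higher for 18 of 18 members (0.19, percentile 100), with Ctsd at 418 and 554 CPM, but did not stand apart at a clustering resolution of 0.4 (0.12, percentile 97.1). Disease-associated microglia genes were higher for 8 of 10 members (0.15, percentile 98.1), led by Spp1 at 17.2 and 27.0 CPM, but no longer stood apart under most other ways of forming or weighting regions, down to 0.07 (percentile 60.0) with regions by marker score. Chaperones were higher for 16 of 18 members (0.20, percentile 100), with Hspa5, the main chaperone of the endoplasmic reticulum, at 173 and 264 CPM.

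Excitatory projection neuron genes were higher in O-Ex for 8 of 9 members, where 70.7% of all genes were higher (median 0.22, percentile 100), with Slc17a7 at 0.29 and the pentraxin Nptx1 at 0.46, though their whole-section median of 0.08 did not stand apart. Synaptic genes were higher for 19 of 24 members (0.10, percentile 99.3), among them the glutamate receptor subunits Gria2 and Grin2b at 0.34 each, and did not stand apart once centred on transcript length (0.07, percentile 86.8). Neurotrophic and exercise-linked genes were higher for 8 of 10 members (0.16, percentile 99.1), with the growth factor Vegfa at 25.2 and 34.8 CPM, and did not stand apart after that centring either (0.13, percentile 95.5). Immediate early genes did not stand apart (0.11, 10 of 15 higher): Egr1 was at 85.6 and 128 CPM, and Arc at 27.8 and 20.1 CPM. Myelin genes were higher for 15 of 16 members within regions (0.18, percentile 99.99), with Cldn11 at 0.53, but had a median of -0.16 over the whole sections. That list did not stand apart at a clustering resolution of 0.4 (0.04, percentile 55.9) or with regions by marker score (0.01, percentile 28.3).

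Respiratory and ribosomal transcripts were lower in O-Ex by small amounts. Nuclear encoded respiratory genes were lower for 54 of 69 members (median -0.12, percentile 0), with Ndufa6 at -0.29 and Cox6c at -0.19, and their median was 0.001 once centred on transcript length. Ribosomal protein genes were lower for 76 of 81 members (-0.08, percentile 0.42), with Rpl41 at -0.19, and their median was 0.02 after that centring. Mitochondrially encoded respiratory genes did not stand apart within regions (-0.08, 12 of 13 lower), but did so as lower over the whole sections (-0.12, percentile 0.845) and in several other alternatives, such as a clustering resolution of 0.4 (-0.14). The other lists that did not stand apart had medians of 0.09 for homeostatic microglia, -0.03 for astrocyte identity, 0.07 for oligodendrocyte precursors, 0.13 for mural cells, 0.03 for GABA interneurons and 0.07 for neurogenesis. Astrocyte identity genes stood apart as lower in several alternatives, with a median of -0.09 (percentile 0.05) at a clustering resolution of 0.4. Over the whole sections GABA interneuron genes stood apart as lower (-0.13, percentile 0.01) and mural genes as higher (0.24, percentile 99.2). Circadian clock genes had a median of 0.10, glucocorticoid response genes 0.03 (mean -0.04), senescence genes 0.10 and cholesterol synthesis genes 0.04. Among lists with too few measured members, Cd74 was at 10.1 CPM in O-Ctrl and 23.2 CPM [22.0 to 24.6] in O-Ex (log2 ratio 0.90 over the whole sections and 0.40 after region matching, higher in 11 of 15 regions), Ighm, the heavy chain of IgM, at 28.5 and 66.2 CPM, Jchain, which joins antibody units, at 0.211 and 4.25 CPM, the heavy chain gene Ighg2c at 3.46 and 3.10 CPM, and Pomc at 8.00 and 6.72 CPM.

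**Figure D4:**
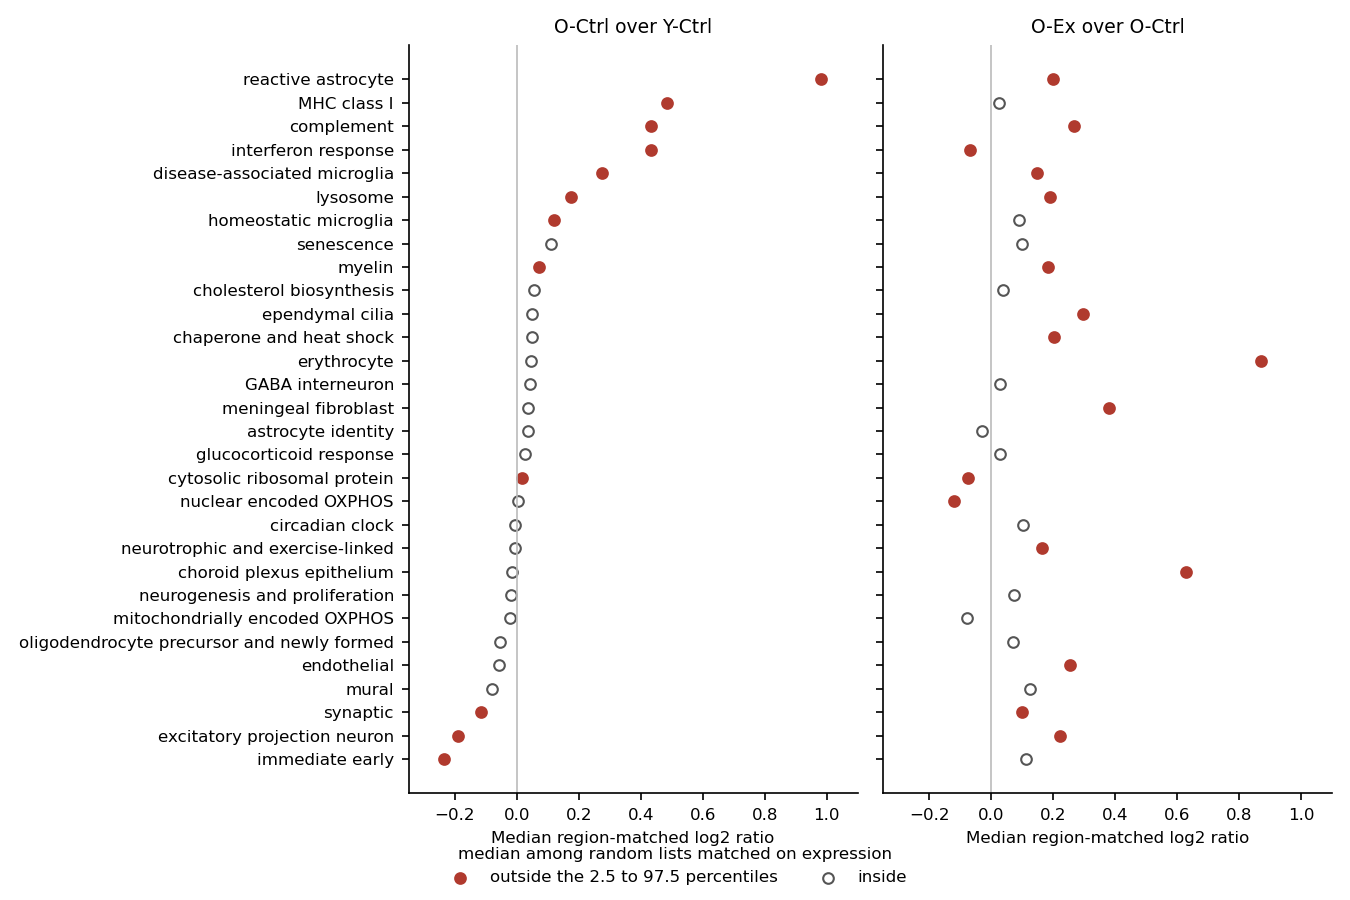
Median region-matched log2 ratio of each of 30 gene lists for O-Ctrl over Y-Ctrl and O-Ex over O-Ctrl, ordered by the first; filled points lie among the lowest or highest 2.5% of random lists matched on expression, open points do not, and no error bars are drawn. Reactive astrocyte genes had medians of 0.98 and 0.20, interferon response genes 0.43 and -0.07 (0.001 in the second comparison over whole sections), and erythrocyte genes 0.04 and 0.87.

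Region by region, genes were again ranked with region markers and sex-linked genes left out. Of these, Gbp2 had the lowest ratio of O-Ex over O-Ctrl in hypothalamus (-2.01), the meninges (-1.99), thalamus (-1.97), layer 6 cortex (-1.84) and upper cortical layers (-1.52). In white matter the lowest ranked gene was its relative Gbp4, at 21.7 CPM [17.6 to 26.5] in O-Ctrl and 4.32 CPM [2.36 to 7.25] in O-Ex. Ttr, left out as a region marker, was lower still there (log2 ratio -1.785, against -1.519 for Gbp4). In the meninges Igkc had 772 of its 2534 counts in O-Ex and 1 in O-Ctrl, or 834 CPM [776 to 895] and 1.00 CPM [0.0254 to 5.58]; Igkc took no part in the clustering. It was at 73.04 CPM of O-Ex in the cluster led by Lypd1, at 56.3 CPM in the ependyma and ventricle wall, and between 1.11 and 21.3 CPM in the other 12 shared clusters. Of the ranked genes Gm47283 was highest in hypothalamus, layer 6 cortex and upper cortical layers (1.39, 1.28 and 1.46). The haemoglobin gene Hba-a1 was highest in thalamus (1.40), and the noncoding RNA Meg3 in white matter (1.38). The unranked Ttr had higher ratios in hypothalamus (2.63), upper cortical layers (1.66) and thalamus (1.51), but not in layer 6 cortex (0.97) or white matter. In the ependyma and ventricle wall Prlr, the prolactin receptor, was highest (103 and 11.7 CPM) and Sag, a visual arrestin, lowest (10.3 and 112 CPM).

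The third question was whether genes that differed with age lay the other way with exercise. Of the 23 genes at least 1.5-fold higher in O-Ctrl than in Y-Ctrl, 11 were lower in O-Ex than in O-Ctrl, 4 of them by at least 1.5-fold: Gbp2, Igtp, AW112010 and Ly6a. O-Ctrl is in both ratios, so genes picked as high in it can lie lower in a section set against it. In 100 simulated sets in which O-Ex did not differ from O-Ctrl, 55.0% of the genes picked this way (53.2 per set on average) were lower in O-Ex. Those sets hold no general shift, whereas 29.3% of all measured genes were lower in the real O-Ex section. They therefore cannot decide whether 11 of 23 is many. With the real O-Ctrl spots split between the ratios, which removes the shared counting error, the share was 45.0%. C4b, Serpina3n, Gfap and Lyz2 were not among the 11, with ratios of 0.35, 0.20, 0.23 and 0.34. Of the 11 genes lower in O-Ctrl, 7 were higher in O-Ex. The share was 57.9% in the simulated sets, 66.2% with O-Ctrl split and 70.7% among all measured genes. Of the region markers among the 11, Ramp3 and Prkcd were higher in O-Ex than in O-Ctrl, and Pmch, Hcrt and Tac2 were lower. Tmem267 was the 1 gene of the 7 that differed by 1.5-fold (14.8, 7.56 and 14.1 CPM in Y-Ctrl, O-Ctrl and O-Ex). Nptx2 (22.9 CPM in O-Ex), Bc1 (8690 CPM) and Shank3 (19.6 CPM) lay between the control sections. Over all 9014 genes the ratios had a Pearson's r of -0.13 and a Spearman's rho of -0.12. O-Ctrl enters both ratios, which by itself gives a negative r: 100 simulated sets of sections without differences gave an r of -0.43. The observed covariance was -0.00252 and the simulated one -0.00205, and the r was -0.02 with the O-Ctrl spots split at random between the ratios.

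**Figure D5:**
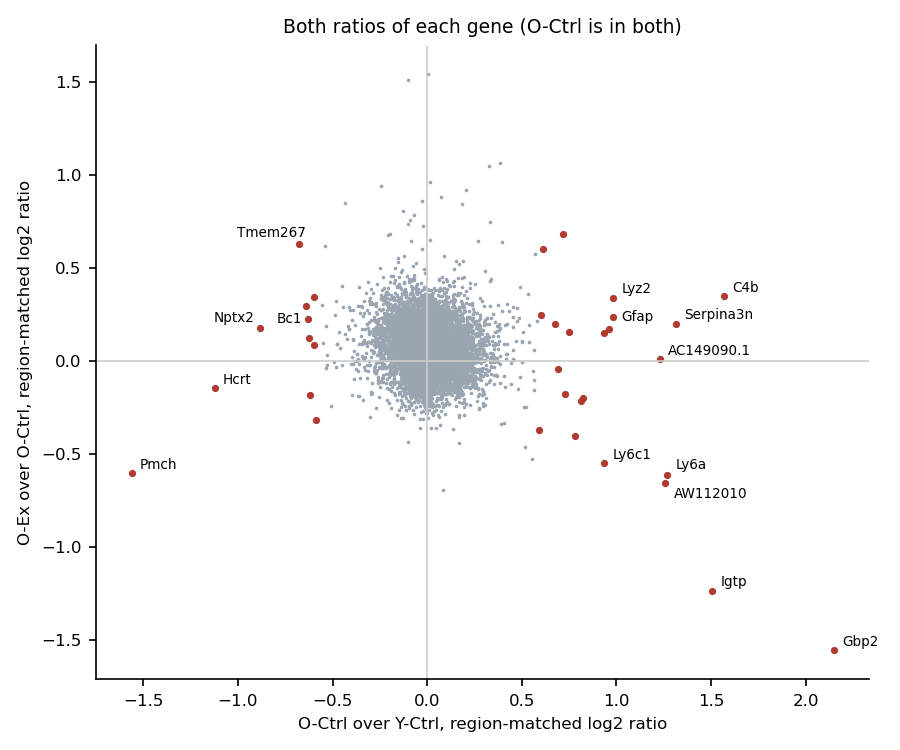
Region-matched log2 ratio of O-Ctrl over Y-Ctrl (x axis) against that of O-Ex over O-Ctrl (y axis), with 1 point for each of 9014 genes and the 34 genes at least 1.5-fold apart on the x axis in red; no error bars are drawn. Gbp2 (2.15, -1.56) and Igtp lie to the lower right, whereas C4b (1.57, 0.35) and Serpina3n lie to the upper right.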

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

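The tests of endothelial cells, of regional make-up, of an even layer of choroid plexus RNA and of centring on transcript length were chosen after the results they bear on were seen. The barcodes with under 200 UMIs, which entered no comparison, numbered 542 in Y-Ctrl, 251 in O-Ctrl and 587 in O-Ex. In those of O-Ex, Ttr took 26266 CPM and Enpp2 3025.1 CPM, above the same barcodes of the control sections, where Ttr was at 5023.8 CPM in Y-Ctrl and 1482.3 CPM in O-Ctrl and Enpp2 at 861 and 174 CPM.

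Choroid plexus transcripts were also higher in O-Ex in regions outside the choroid plexus, with Ttr at 549 CPM in Y-Ctrl, 992 CPM in O-Ctrl and 2058 CPM in O-Ex, but in white matter Ttr was lower in O-Ex (5543 and 1605 CPM). More Ttr per choroid plexus cell relative to other choroid genes is argued against. Inside the choroid plexus cluster, Ttr less the median of 9 other choroid genes was -0.111 (log2, O-Ex over O-Ctrl). A rise of all choroid genes together would not show in this measure, and Ttr itself had a log2 ratio of 0.10 there. An even layer of choroid plexus RNA is argued against as the whole cause: the excess of Ttr UMIs per spot in the cluster led by Lypd1 (462 and 18730 CPM in O-Ctrl and O-Ex) was 82.6 times the median of the shared regions, while a cluster led by Tshz2 was at 297 and 335 CPM. Choroid plexus RNA spread unevenly over parts of the section is a candidate explanation, though not for white matter. By UMIs per spot, O-Ex less O-Ctrl, Ttr was lower in white matter (-48.5) and also in the shared cluster of low depth (-33.6). In this low-depth cluster its CPM was higher in O-Ex (8946 and 17700 CPM in O-Ctrl and O-Ex). For such a spread, the 9 genes' excess outside the choroid plexus cluster departed from their ratio to Ttr inside it by a median of 0.347 on the log2 scale (from -0.303 for Kcne2 to 1.46 for Otx2). Choroid plexus tissue inside spots of other clusters would give the same ratios, and that, like an effect of exercise, was not tested.

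Gbp2, Igtp, AW112010, Ly6a and Ly6c1 were higher in O-Ctrl than in the other 2 sections. A larger share of endothelial cells is argued against, because the 11 other endothelial genes had a median log2 ratio of -0.0977 in O-Ctrl over Y-Ctrl (from -0.475 to 0.158). Region matching, which moved Cck from -0.24 to -0.53, left the median ratio of the 5 genes at 1.27, against 1.22 over the whole sections. Their median ran from 0.662 to 2.14 across the shared regions, so their difference lay within regions. However, Gbp2, Igtp, AW112010 and Ly6a had been named for high region-matched ratios with 1 direction in every region. That outcome was thus set by the choice of genes and is no separate test of a regional make-up of its own for O-Ctrl. A list of 23 interferon-gamma-induced genes was added for this test, with 22 of them in the files and 1 at the minimum of 10 CPM. It was at 36.4 CPM in Y-Ctrl, 125 CPM in O-Ctrl and 52.5 CPM in O-Ex, 2.38 times higher in O-Ctrl than in O-Ex. This was the outcome predicted for an interferon-gamma-induced state of the O-Ctrl section. The list was written after Gbp2 and Igtp had been seen, and many of its members are their Gbp and immunity-related GTPase relatives. It is therefore not separate from the genes that prompted it, and the kind of interferon was not tested. Whether age, exercise or this 1 animal lay behind the high level in O-Ctrl could not be separated with 1 section per group.

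Most differences between O-Ex and O-Ctrl were small after averaging over the shared regions, with 99.6% of genes within 1.5-fold. GC content is argued against as their source, with a Spearman's rho of -0.0478 across 9009 genes. Transcript length had a rho of 0.352 with the ratio, so a bias by length, as a difference in RNA quality might give, is a candidate explanation for part of them. Centring on genes of like length left Gbp2 at -1.53 and turned no named gene, and an effect of exercise on long genes remains untested. For O-Ctrl over Y-Ctrl the rho was 0.159 with GC content and -0.093 with length. Whether either shaped that comparison was not tested.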

How the results depend on the processing

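Chosen after the results were seen were the settings without the shared cluster of low depth, without the named genes in clustering, with O-Ctrl split, without mitochondrial genes in list medians, and centred on transcript length. For no result below was the cause of a move tested, except where fewer or more genes enter by construction. No paired analysis was possible because each group has 1 section.

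Against 55 genes at least 1.5-fold apart in the whole-section age comparison there were 93 with a mean of at least 2 CPM, 19 with at least 50 CPM and 16 at 2-fold. Against 75 for exercise there were 18 and 25 for the last pair. Against 34 region-matched genes for age there were 54, 15 and 9, with 70 at a pseudocount of 1 and 53 with thinned spots. Against 34 for exercise there were 14 with at least 50 CPM, 6 at 2-fold, 68 at a pseudocount of 1 and 52 with thinned spots.

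The correlation of -0.132 between the comparisons was -0.0198 over whole sections, -0.205 with at least 2 CPM, -0.0732 with no scaling within sections and -0.156 with regions by marker score. It was -0.0935 without the shared cluster of low depth, -0.113 with clustering without the named genes and -0.113 when centred on transcript length. It ran from -0.179 to -0.0935 when shared regions were left out in turn, and was -0.0245 with O-Ctrl split.

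Of 900 list medians under alternatives, 716 kept their direction and their side of the percentile limits, 40 no longer stood apart and 54 newly did, each with the same sign, and 8 of lists that stood apart changed sign. The other 82, of lists that did not stand apart, changed sign too, and 9 of them then stood apart. In age, synaptic genes were at 0.0041 with no scaling within sections, and ribosomal genes at -0.0068 at a resolution of 1.5, -0.0136 with no scaling and -0.0029 with weighted regions. In exercise, interferon genes were at 0.0014 and myelin genes at -0.164 over whole sections, and nuclear respiratory genes at 0.00076 and ribosomal genes at 0.0163 after length centring. Over whole sections 19 lists stood apart in age, against 12. Of 480 values of named genes, 404 stayed within the counting error of the main value and 76 moved past it. Among those of genes at least 1.5-fold apart 0 changed sign, and a change of sign was not counted for smaller ratios. The genes had been picked for 1 direction over the whole section and the shared regions, which favours a steady sign.

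White matter took 13.7%, 15.8% and 11.96% of spots in Y-Ctrl, O-Ctrl and O-Ex by marker score, and 10.2% in O-Ctrl and 8.49% in O-Ex with at least 1000 UMIs. Choroid plexus took 3.76%, 3.14% and 4.33% at a resolution of 0.4, 2.58%, 2.92% and 4.40% with no scaling, 2.04%, 2.34% and 6.76% by marker score, and 4.10%, 2.76% and 5.80% with at least 1000 UMIs. The median of O-Ex was 11518.5 UMIs per spot with at least 1000 UMIs and 13685 with at least 3000. Depth itself was varied by thinning the spots, with the counts given above.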

Other observations

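The interferon-gamma list used above was added after Gbp2 and Igtp had been seen. Its members were written down before the values of the list were looked up, but Gbp4 is also a region extreme of the main results. Gbp4 and Gbp3, guanylate-binding proteins, which attack vacuoles of intracellular pathogens, had their highest level in O-Ctrl: Gbp4 was at 1.46 CPM [1.17 to 1.79] in Y-Ctrl, 15.7 CPM [14.6 to 16.7] in O-Ctrl and 3.71 CPM [3.21 to 4.26] in O-Ex, and Gbp3 at 3.02, 13.4 and 6.30 CPM. Immunity-related GTPases followed, with Iigp1 at 1.28, 10.4 and 2.07 CPM and Ifi47 at 1.31, 10.00 and 2.79 CPM. Irf1, a transcription factor of the pathway, was at 3.48, 8.09 and 5.005 CPM, and Cd274, the ligand of an immune checkpoint receptor, at 1.28, 5.77 and 1.60 CPM. Ido1, a tryptophan-degrading enzyme, was at 2.30, 1.51 and 0.470 CPM, and Socs1, an inhibitor of the pathway, at 2.72, 3.05 and 2.54 CPM.

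Some class II and neutrophil transcripts, chosen after their values were seen, were lowest in Y-Ctrl and highest in O-Ex. H2-Ab1, a class II chain, was at 2.54 CPM [2.16 to 2.97], 6.93 CPM [6.26 to 7.65] and 11.2 CPM [10.3 to 12.1], and S100a8, a calcium-binding protein of neutrophils, at 0.744, 1.77 and 3.41 CPM. Ciita, the activator of class II genes, had 2, 17 and 6 counts, and H2-DMa was at 12.5, 13.02 and 14.3 CPM. Of T cell genes, Cd3d had 7, 17 and 15 counts, Cd3e 2, 3 and 5, Cd8a 1, 9 and 6, and Cd4 42, 32 and 16.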
